A study of Mus musculus with 15 samples.

How the data were processed

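Hemibrain RNA was measured on 15 Agilent 2-colour mouse arrays, 5 per diet and 1 animal per array. The hemibrain sample was labelled with Cy5 and the reference pool with Cy3 on every array, so a dye effect is shared by all arrays and was not estimated. Total RNA was extracted with Trizol and amplified with a 2-colour kit, per the labels. Groups were taken from the diet given for each sample, since the titles carry the word control in all 3 groups. DNA methylation and microRNA were not analysed here, and the values of a few genes are not reported here.

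The deposited scanner files hold spot intensities, per the file headers as median pixel intensities of the spot and of the local background in each channel, and as processed intensities that are background-subtracted, spatially detrended and dye-normalized. The values deposited with the series are log10 ratios of Cy5 over Cy3 after background subtraction and dye normalization, equal to the log10 ratios in the scanner files. The spots were quantified with Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 10.7. The headers name an older genome build than the gene reference used here, so genes are given by symbol without coordinates.

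Median spot intensities were corrected for background with the normexp method (offset 50) and normalized by loess within each array, with control spots given no weight, in limma 3.58.1 under R 4.3.3. Spots marked by the scanner software as outliers (0.57%) were left out, spots of the same probe were averaged, and probes well above background in Cy5 on at least 5 of the 15 arrays and with at least 8 values were kept. This left 26348 probes before the minimum of values. Of 55681 probes on the array, 27656 could be given a gene symbol. Each symbol was represented by its probe with the highest mean Cy5 level, and probes without a symbol were kept singly, which gave 22557 genes tested, 13763 with a symbol and 8794 without. Tables were handled with the data.table package (version 1.17.8), and Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

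A single limma model over all 15 arrays, with 12 residual degrees of freedom, gave the 3 pairwise comparisons of diets and a moderated F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the p of pairwise comparisons are 2-sided. The sets were 44 lists of pathways, cell types and brain regions, of which 43 had at least 5 measured genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with the correlation estimated from the residuals. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 genes with a symbol and the largest increase and the 12 with the largest decrease among those past the threshold, filled up with the genes of lowest unadjusted p where fewer passed. It added up to 4 members that passed, or else the 2 members of lowest unadjusted p, of each list described, the 5 genes of lowest p in the F test, and always Fads1, Fads2, Elovl2, Elovl5, Mfsd2a and Bdnf.

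Results were recomputed under 41 alternative settings as far as each applied, 33 of them for lists and up to 35 for single genes. Among them were each array left out in turn, other background and dye normalizations, Cy5 alone, other filters and probe summaries, and slide or scan day as a block. Slide and scan day came from the array barcodes and scan times in the files. The number of arrays limits the precision, and the median standard error of a log2 change between diets was 0.163. The analysis was tested on simulated arrays with the spread of the real ones and 50 genes changed by each size. With log2 changes of 0.5, 1, 1.5 and 2 it recovered 16%, 72%, 94% and 96% in ERD against STD, 16%, 78%, 96% and 96% in BLD against STD, and 28%, 70%, 94% and 98% in ERD against BLD. Unchanged genes made up 5.4%, 5.3% and 4% of the calls, the 1 shifted list was found each time, and 0 of 20 unshifted lists were called. The simulated lists were random genes with independent noise, so they do not test list calls where genes of a list are correlated. Each gene had the same spread in all diets, and slide and scan day had no effect. The simulated share of unchanged genes among the calls therefore need not hold for the real arrays.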

Results

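Left hemibrain total RNA of male C57BL/6J mice was profiled on Agilent mouse arrays after 24 weeks, from 3 weeks of age, on 1 of 3 diets of equal caloric content. The diets differed in their ratio of n-3 to n-6 polyunsaturated fatty acids (PUFA), which was 7 to 1 in the enriched diet (ERD), 1 to 1 in the balanced diet (BLD) and 1 to 6 in the standard diet (STD). Each diet had 5 arrays, each with the hemibrain of 1 animal in Cy5 and the same reference RNA, a pool of 11 mouse cell lines, in Cy3. A value is therefore the log2 ratio of hemibrain to reference, and diets are compared through the reference. Between 17720 spots (ERD 1) and 31991 spots (BLD 4) per array were well above background in Cy5. The means were 26949 ± 1612 for STD, 27945 ± 3535 for BLD and 24692 ± 4193 for ERD (SD, n = 5). The STD arrays resembled each other more (median pairwise r across genes 0.973) than the BLD arrays (0.931) or the ERD arrays (0.928). The least correlated arrays were ERD 1, BLD 3 and ERD 4, with median r to all others of 0.88, 0.911 and 0.914. Arrays came from 8 slides and 2 scan days, and the later day held 3 BLD arrays, 1 ERD array and 0 STD arrays.

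**Figure D1:**
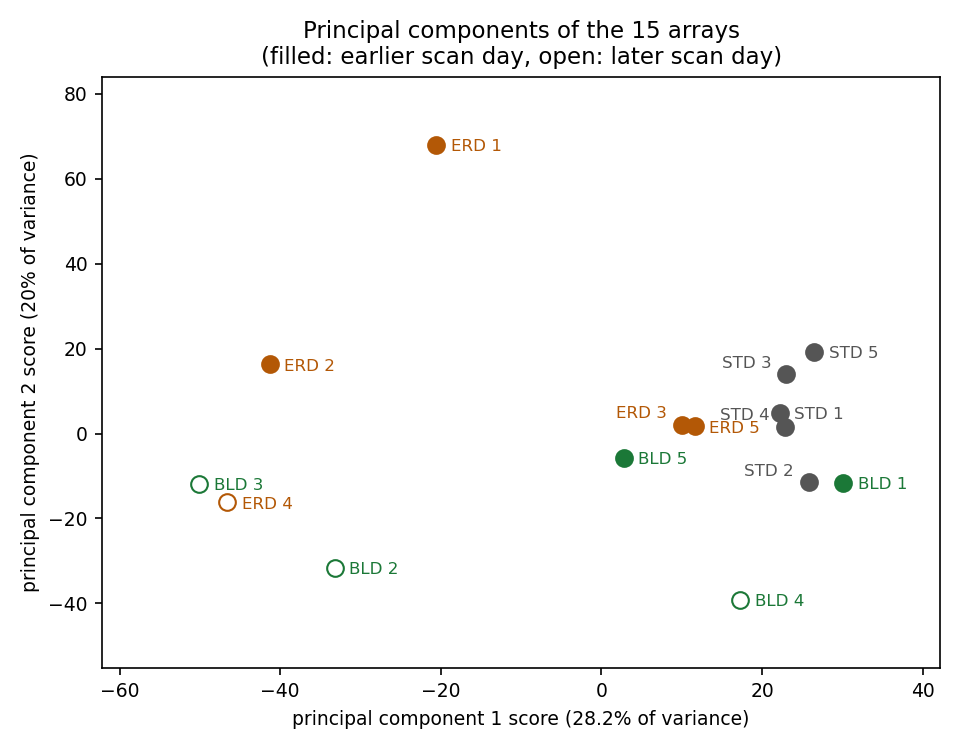
Scores of the 15 arrays on principal component 1 (28.2% of variance, horizontal) and principal component 2 (20%, vertical) of the log2 ratios of all genes tested, with 1 point per array, coloured by diet, filled for the earlier and open for the later scan day. The 5 STD arrays lay together at component 1 scores from 22.2 to 26.5, whereas ERD arrays ran from -46.6 to 11.6 and BLD arrays from -50.1 to 30.1. The lowest scores were those of ERD 4, BLD 2 and BLD 3, all on slide 1, and of ERD 2. ERD 1 stood apart on component 2 at 67.9.

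The comparison of ERD with STD asks which hemibrain transcripts differ between the n-3 enriched and the standard diet. Raly, which encodes an RNA-binding protein of the hnRNP family, was 4.07-fold higher in ERD, with a log2 change of 2.02 ± 0.22 (SE). Its group means were 0.56 ± 0.27 in ERD and -1.47 ± 0.58 in STD (SD, n = 5 each). Cntfr, the ligand-binding receptor of ciliary neurotrophic factor, was 3.64-fold higher. Puf60, a splicing factor, was 2.05-fold higher and Eif4g1, the scaffold of the translation initiation complex, 1.88-fold higher. Among the genes that fell, Creg2, a secreted glycoprotein of the brain, fell by 1.61 on the log2 scale, Eml2, a microtubule-associated protein, by 1.37, and Klhl9, an adaptor of a ubiquitin ligase, by 1.13. In each of these 7 genes the values of the 5 ERD and the 5 STD arrays did not overlap. The reference in Cy3 also differed between ERD and STD, by 0.84 for Cntfr and -0.71 for Creg2, with 0 genes called there. From Cy5 alone Cntfr was at 2.41 and Creg2 at -1.95, so both channels moved in the direction of the ratio. For Raly, Puf60, Eif4g1, Eml2 and Klhl9 the change in Cy3 lay between -0.21 and 0.08.

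In limma, 49 of 22557 genes passed an adjusted p of 0.05 between ERD and STD, 24 higher and 25 lower in ERD. Of these, 39 had a gene symbol. The adjusted p values were 0.0027 for Raly, 0.0477 for Cntfr, 0.00879 for Puf60 and for Eif4g1, 0.0401 for Creg2, 0.0176 for Eml2 and 0.0292 for Klhl9. An unadjusted p under 0.05 was reached by 3302 genes (14.6%). The arrays of both diets did not overlap in 3.78% of genes, where chance gives 0.79%. BLD lay between STD and ERD in 44 of the 49 genes, a count that arrays simulated without any effect gave as well (mean 45.7). The other genes with the largest increases were Anp32a (0.98), Lsm14b (0.95), Cep250 (0.89), Rhog (0.80), Ube4a (0.78), Rnf10 (0.76), Prdx5 (0.75) and Mrnip (0.70, log2), with adjusted p between 0.0173 and 0.0477. Prdx5 is a peroxiredoxin that removes peroxides, and Rhog is a small GTPase that acts on the actin cytoskeleton. The other genes with the largest decreases were Ndn (-1.10), Srp9 (-1.05), Tmem59 (-0.95), Nsd2 (-0.91), Ei24 (-0.83), Acap2 (-0.79), Cnot6l (-0.76) and Strap (-0.74), with adjusted p between 0.0292 and 0.0477. Ndn encodes necdin, an imprinted growth suppressor of neurons, and Cnot6l a deadenylase of messenger RNA. From the processed signals Ube4a was at 1.22 and Ei24 at -1.48. Of these genes Acap2 alone had overlapping groups, and Ei24 was above background on 4 of the 5 ERD arrays.

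Other probes of the same gene did not always move with the probe tested. Raly, Cntfr, Puf60, Eif4g1, Creg2 and Klhl9 had no further measured probe, so each rests on a single probe that could not be compared. Eml2 and Tmem59 had a further probe in the same direction (-1.70 and -0.64), whereas the further probes of Srp9 (-0.19) and Strap (-0.16) moved less. Those of Anp32a (-0.04), Lsm14b (-0.31), Nsd2 (0.02 to 0.14) and Cnot6l (0.01) did not follow the called probe. Transcripts without a gene symbol were among the 49 as well, and the 2 named here were chosen after their values were seen. The probe A_66_P101646 fell by 2.61 (adjusted p = 0.0173), but by 1.69 from Cy5 alone (adjusted p = 0.089), while the reference in Cy3 was higher by 0.71 (adjusted p = 0.699), and the probe A_55_P2037525 was higher by 1.08 (adjusted p = 0.00437).

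Raly, Puf60 and Eif4g1 stayed past the threshold whichever array was left out, with highest adjusted p of 0.0153, 0.0405 and 0.0405. Rnf10 lost its call without ERD 4 or STD 4, and Eml2 without ERD 4 or STD 3, each with a highest adjusted p of 0.0727. The other 19 of the 24 genes taken by the rule for named genes lost theirs without between 6 and 13 of the arrays. Of these 24 genes, 21 lost their call without ERD 4, 19 each without BLD 2, STD 3 or STD 4, and 18 each without STD 2 or STD 5. The number was 17 without STD 1, 16 without BLD 4, 14 without ERD 2, 9 without ERD 5, 8 without ERD 1 and 7 without BLD 5. It was 1 without BLD 1 and 0 without ERD 3 or BLD 3. For genes past the threshold, ERD against STD, the count of 49 became 5 without ERD 4, 170 without ERD 3, 21 without ERD 2 and 18 without STD 1. It became 15 without BLD 4, 11 without STD 3 and 9 without any 1 of BLD 2, STD 2, STD 4 or STD 5. With slide as a fixed block the median change of the 49 genes was 0.93 of its size and 0 of them passed (Raly 1.88, adjusted p = 0.105). With scan day as a fixed block 11 of them passed (Raly 2.03, adjusted p = 0.00834). On slides 4, 5 and 7, which each held 1 ERD and 1 STD array, Raly was at 2.47, 1.37 and 1.67, Cntfr at 2.32, 1.51 and 1.63, and Creg2 at -0.85, -1.57 and -1.72.

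**Figure D2:**
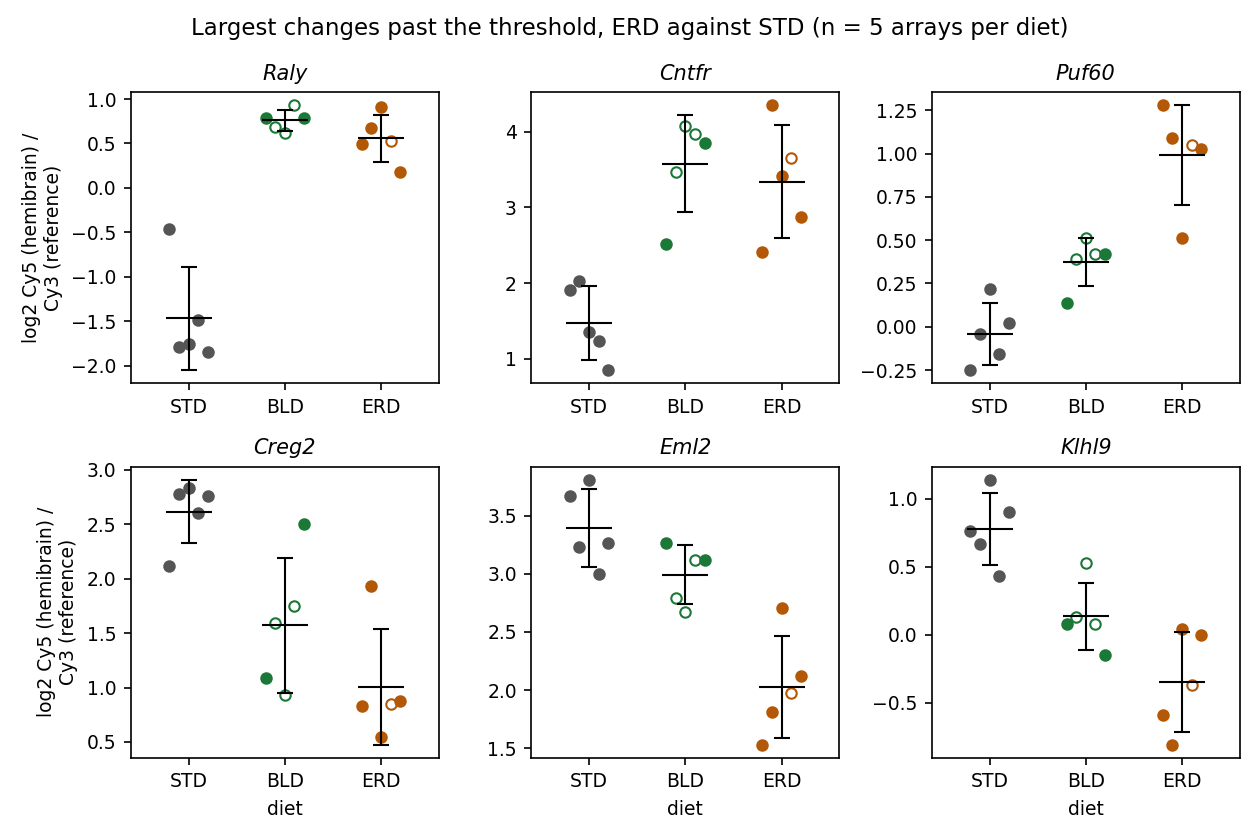
Log2 ratio of hemibrain (Cy5) to reference (Cy3) per array (vertical) by diet (horizontal) for the 3 named genes with the largest increases and the 3 with the largest decreases in ERD against STD. Points are single arrays, open for the later scan day, with the mean and SD of 5 arrays; STD and ERD arrays do not overlap in these 6 genes, as in Raly with means of -1.47 (STD), 0.76 (BLD) and 0.56 (ERD).

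Genes of long-chain PUFA synthesis, the pathway of desaturation and elongation for which n-3 and n-6 precursors compete, fell in ERD against STD. Of 18 measured members 14 were lower, with a median log2 change of -0.08 and a mean of -0.22. The list mean was lower on each of the 5 ERD arrays (-0.18 to -0.07) than on any STD array (0.03 to 0.15). The camera test gave an adjusted p of 0.0285, and adjusted p = 0.329 with an estimated correlation. The members with the lowest unadjusted p were Elovl4 (-1.14, adjusted p = 0.188) and Hacd1 (-0.38, adjusted p = 0.218). None (0 members) passed adjusted over the list alone, with 4 at an unadjusted p under 0.05. Fads1, the delta-5 desaturase, had a log2 change of -0.63 ± 0.24 (adjusted p = 0.242 in limma), Elovl2 -0.50 (0.441), Elovl5 -0.08 (0.772) and Fads2, the delta-6 desaturase, -0.09 (0.707). Fads2 was above background on 5 STD, 2 BLD and 1 ERD arrays, so that a difference in it was hardly measurable. From the processed signals of the scanner software Fads1 was at -1.06, Fads2 at -0.86, Elovl2 at -0.81, Elovl5 at 0.07 and Bdnf at -0.47, and from Cy5 alone Elovl5 was at 0.16. Mfsd2a, the transporter of docosahexaenoic acid at the blood-brain barrier, had a change of 0.52 (adjusted p = 0.274) and Bdnf one of -0.23 (0.369). The long-chain PUFA synthesis list had a median of -0.13 without ERD 1, -0.05 without ERD 2 and -0.20 without ERD 3. It lost its call without ERD 4 (median -0.13, adjusted p = 0.0526), with slide as a block (-0.18, adjusted p = 0.0587) and with scan day as a block (-0.09, adjusted p = 0.0513). Within slides 4, 5 and 7 its median was -0.14, -0.10 and -0.16.

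**Figure D3:**
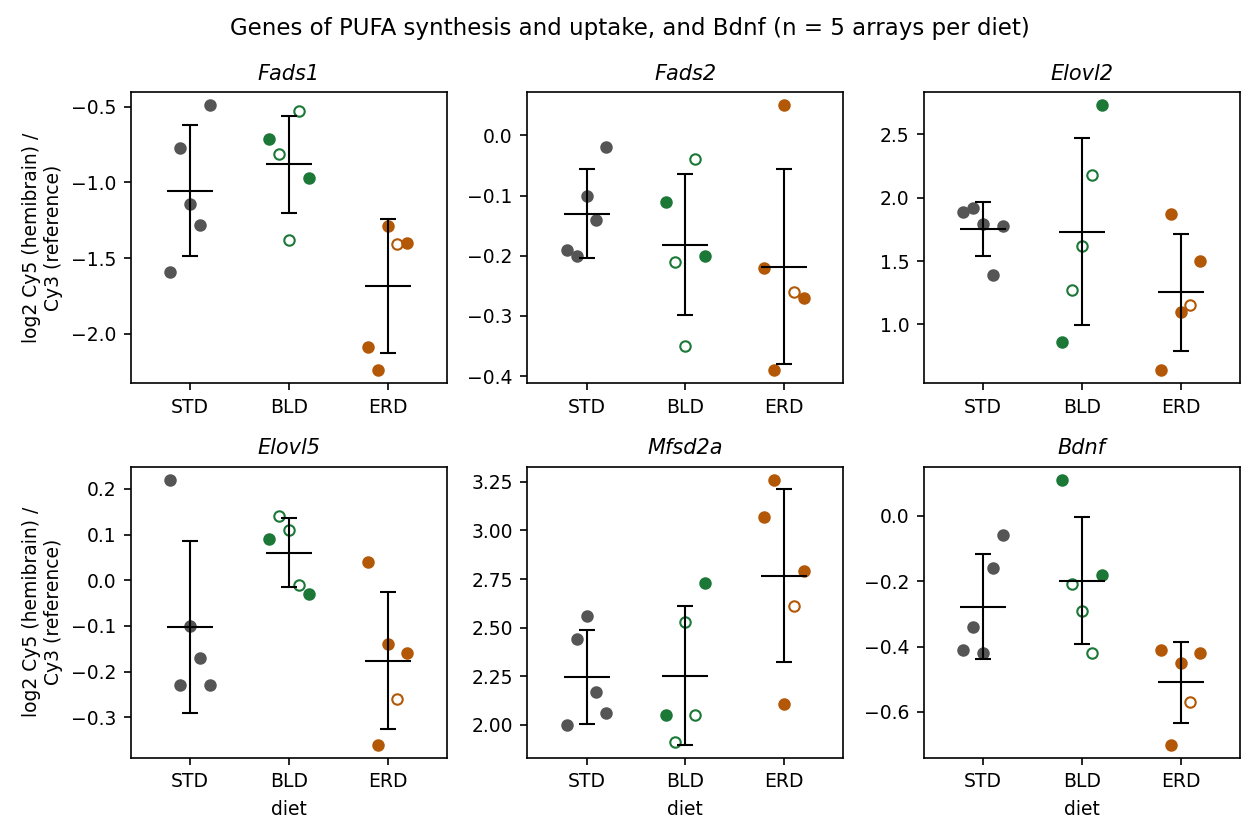
Log2 ratio of hemibrain (Cy5) to reference (Cy3) per array (vertical) by diet (horizontal) for 5 genes of PUFA synthesis and uptake and for Bdnf, named whatever their values. Points are single arrays, open for the later scan day, with the mean and SD of 5 arrays; STD and ERD arrays overlap in all 6 genes, as in Fads1 with means of -1.06 (STD), -0.88 (BLD) and -1.69 (ERD).

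Genes of fatty acid oxidation and targets of the PPAR receptors rose in ERD against STD. Of 28 measured members 20 were higher, with a median of 0.12. The list mean was higher on each ERD array (0.01 to 0.10) than on any STD array (-0.12 to -0.05). The adjusted p was 0.0412 in camera, and adjusted p = 0.434 with an estimated correlation. Hadha, a subunit of the mitochondrial trifunctional protein of beta-oxidation, had a change of 0.43 (adjusted p = 0.0753), and Plin4, a lipid droplet protein, one of 0.84 (adjusted p = 0.0858). Adjusted over the list alone 3 members passed, all higher, and 0 over all genes in limma, with 4 at an unadjusted p under 0.05. The call was lost without ERD 1, ERD 3, ERD 4, STD 1, STD 2 or STD 5 (highest adjusted p 0.11), with slide as a block (0.08, adjusted p = 0.279) and with scan day as a block (0.08, adjusted p = 0.0659). The list also lost it without the 3 least correlated arrays (0.04, adjusted p = 0.173), without slide 3 (0.12, adjusted p = 0.117) and with Cy5 detection as a covariate (0.10, adjusted p = 0.156). Within slides 4, 5 and 7 its median was 0.09, 0.08 and 0.01.

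The endocannabinoid system, whose ligands are made from arachidonic acid, fell in ERD, with 13 of 16 measured genes lower and a median of -0.41. The adjusted p was 0.000498 in camera, and adjusted p = 0.329 with an estimated correlation. Abhd4 (-0.52, adjusted p = 0.145) and Dagla (-0.56, adjusted p = 0.164), which act in the synthesis of anandamide and of 2-arachidonoylglycerol, had the lowest unadjusted p. Adjusted over the list alone 4 members passed, all lower, while 0 passed over all genes in limma and 8 had an unadjusted p under 0.05. The call held whichever array was left out. The median was -0.27 with slide as a block (adjusted p = 0.0213) and -0.38 with scan day as a block (adjusted p = 0.0016). Within slides 4, 5 and 7 it was -0.16, -0.64 and 0.05.

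Synaptic genes fell in ERD against STD. Of the glutamatergic synapse 31 of 40 genes were lower (median -0.29, adjusted p = 0.00735 in camera, and adjusted p = 0.621 with an estimated correlation). Of the GABAergic synapse and interneurons 25 of 28 were lower (median -0.26, adjusted p = 0.00434, and adjusted p = 0.53 with an estimated correlation). Of synaptic vesicle release 23 of 30 were lower (median -0.15, but 0.02 from Cy5 alone, adjusted p = 0.0462, and adjusted p = 0.659 with an estimated correlation). Of the activity-regulated immediate early genes 19 of 23 were lower (median -0.17, adjusted p = 0.0153, and adjusted p = 0.434 with an estimated correlation). Among the members with low unadjusted p were Homer2 (-0.96, on 4 of 5 ERD arrays above background) and the GABA receptor subunit Gabra3 (-0.64). In the other lists they were Synj1 (-0.50, on 3 ERD arrays) and Syt2 (on 0 ERD and 4 STD arrays, so the size of its change was not measured), and the transcription factors Egr4 (-1.03) and Egr2 (-0.49). None of these passed over all genes in limma, with adjusted p between 0.109 and 0.272. Adjusted over the list alone, 2 glutamatergic genes, 1 immediate early gene and 0 of the GABAergic and vesicle genes passed. In the same order 7, 4, 9 and 5 had an unadjusted p under 0.05. The shift of the glutamatergic and GABAergic genes was largest on ERD 1, with list means of -0.84 and -0.94, whereas both lists were at 0.18 on ERD 2, above the STD means of 0.08 and 0.06. Without ERD 1 the medians were -0.15 (adjusted p = 0.125) and -0.10 (adjusted p = 0.0562). The glutamatergic median was also -0.15 without ERD 3 and -0.16 without STD 2, and the GABAergic one -0.43 without ERD 2. With Cy5 detection as a covariate the glutamatergic and GABAergic medians were -0.11 and -0.14 (adjusted p 0.188 and 0.107 in camera). From Cy5 alone these 2 medians were -0.13 and -0.11 (adjusted p 0.464 and 0.465). The vesicle median was -0.08 without ERD 1, and that of the immediate early genes -0.28 without ERD 1 and -0.09 without STD 1. The immediate early genes lost their call without STD 5 (-0.15, adjusted p = 0.0752). The vesicle genes lost theirs without ERD 1, ERD 4, ERD 5, BLD 2, BLD 5, STD 1, STD 2 or STD 3 (highest adjusted p 0.241). With slide as a block the medians of the glutamatergic, GABAergic, vesicle and immediate early genes were -0.25, -0.34, -0.18 and -0.24 (adjusted p 0.0726, 0.00729, 0.137 and 0.0308). With scan day as a block they were -0.28, -0.28, -0.13 and -0.17 (0.00721, 0.00234, 0.0801 and 0.0196). Within slide 4 they were -0.13, -0.10, -0.08 and -0.25, within slide 5 -0.42, -0.50, -0.15 and -0.24, and within slide 7 0.00, -0.03, -0.19 and -0.05.

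Markers of astrocytes, of the hippocampus and of the olfactory bulb fell as well, while the lists of the other 6 brain regions did not pass (adjusted p 0.0568 to 0.918). Of the astrocyte markers 16 of 20 were lower (median -0.21, adjusted p = 0.0337 in camera, and adjusted p = 0.434 with an estimated correlation). Of the hippocampal markers 11 of 15 were lower (median -0.19, adjusted p = 0.0263, and adjusted p = 0.434 with an estimated correlation), and of the olfactory bulb markers 17 of 21 (median -0.18, adjusted p = 0.0285, and adjusted p = 0.658 with an estimated correlation). The astrocyte markers did not all move one way. Gfap, the intermediate filament of reactive astrocytes, was at 1.04 (adjusted p = 0.121 in limma) and Aldoc, a glycolytic enzyme, at -0.61 (adjusted p = 0.142). Both passed adjusted over the list alone, 0 members passed over all genes, and 5 had an unadjusted p under 0.05. Among hippocampal markers Pou3f1 (-0.76) and Fibcd1 had the lowest unadjusted p, but Fibcd1 was above background on 0 ERD and 4 STD arrays, so the size of its change was not measured. Calb2 (-0.43, on 4 of 5 ERD arrays) and Trh (-0.74) had the lowest p of the olfactory bulb markers. In either list 0 members passed over all genes in limma or adjusted over the list alone, with 3 of each at an unadjusted p under 0.05. The calls were lost without ERD 1, ERD 3, ERD 4 or STD 2 for astrocytes (highest adjusted p 0.122) and hippocampus (0.09), and also without STD 5 for the olfactory bulb (0.104). The olfactory bulb median was -0.34 without ERD 2, -0.08 without ERD 3 and -0.28 without STD 1. With slide as a block the medians were -0.20, -0.20 and -0.18 (adjusted p 0.0792, 0.0726 and 0.0726). With scan day as a block they were -0.22, -0.20 and -0.20 (0.0649, 0.0277 and 0.0277). Within slides 4, 5 and 7 they were -0.13, -0.34 and 0.02 for astrocytes, -0.01, -0.45 and -0.09 for the hippocampus, and 0.15, -0.30 and -0.01 for the olfactory bulb.

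Interferon response genes rose in ERD against STD, with 20 of 26 higher and a median of 0.23 (adjusted p = 0.00163 in camera, and adjusted p = 0.434 with an estimated correlation). Lgals3bp, a secreted binding partner of galectins, had a change of 0.54 (adjusted p = 0.0507), and Bst2, which tethers virus particles, one of 0.54 (adjusted p = 0.128). Both passed adjusted over the list alone, 0 passed over all genes in limma and 8 had an unadjusted p under 0.05. The interferon call held whichever array was left out, although the median was 0.14 without ERD 1 (adjusted p = 0.0217). It held with slide as a block (0.17, adjusted p = 0.0353) and with scan day as a block (0.21, adjusted p = 0.00234). It was lost with the processed signals (0.07, adjusted p = 0.235), with Cy5 alone (0.07, adjusted p = 0.336) and with a normexp offset of 1 (0.13, adjusted p = 0.0632). The medians within slides 4, 5 and 7 were 0.02, 0.23 and 0.20.

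Genes of the circadian clock fell in ERD against STD, with 15 of 20 lower and a median of -0.13 (adjusted p = 0.0337 in camera, and adjusted p = 0.434 with an estimated correlation). Those of the heat shock and unfolded protein response fell too, with 18 of 27 lower and a median of -0.13 (adjusted p = 0.0347, and adjusted p = 0.434 with an estimated correlation). Nr1d2, a repressor of the clock, was at -0.58 (adjusted p = 0.109), above background on 4 of 5 ERD arrays. Of the chaperones, Dnajb9 was at -0.68 (adjusted p = 0.117) and Hspb1 at -0.67 (adjusted p = 0.14). Adjusted over the list alone 1 clock gene and 3 chaperone genes passed, all lower, and 0 over all genes in limma, with 4 and 5 at an unadjusted p under 0.05. The clock genes lost their call without ERD 1, ERD 4 or STD 5 (highest adjusted p 0.122), and their median was -0.20 without ERD 2. The chaperone genes lost theirs without ERD 2, ERD 4, STD 1, STD 3 or STD 4 (highest adjusted p 0.188, with a median of -0.07 without ERD 2). With slide as a block the medians were -0.10 (adjusted p = 0.279) and -0.23 (adjusted p = 0.000203). With scan day as a block they were -0.10 (adjusted p = 0.0659) and -0.14 (adjusted p = 0.0277). Within slides 4, 5 and 7 they were -0.14, -0.09 and 0.04 for the clock and -0.35, -0.20 and -0.23 for the chaperones.

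In all, 13 of 43 lists passed in ERD against STD, 11 lower and 2 higher. With an estimated correlation 0 of them passed, and 0 with the processed signals of the scanner software, where the spread of changes was wider. With those signals the median was -0.60 for the hippocampus, -0.16 for PUFA synthesis, -0.31 for the immediate early genes, -0.20 for the clock, -0.39 for the GABAergic synapse, -0.13 for astrocytes and 0.07 for interferon response. The count of gene lists past the threshold, ERD against STD, became 5 without ERD 4, 6 without ERD 1, 8 without STD 2 and 20 without ERD 2. The other 30 lists had medians between -0.14 and 0.18. Cytokines and acute inflammation came closest, with 17 of 19 genes higher and a median of 0.18 (adjusted p = 0.0502), and cholesterol synthesis had 18 of 24 genes higher with a median of 0.11 (adjusted p = 0.114). Markers of microglia (median 0.05, although the test leaned lower, adjusted p = 0.823), of endothelium (-0.03, adjusted p = 0.388), of blood (0.01, adjusted p = 0.823) and of choroid plexus (-0.01, although the test leaned higher, adjusted p = 0.834) did not pass.

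**Figure D4:**
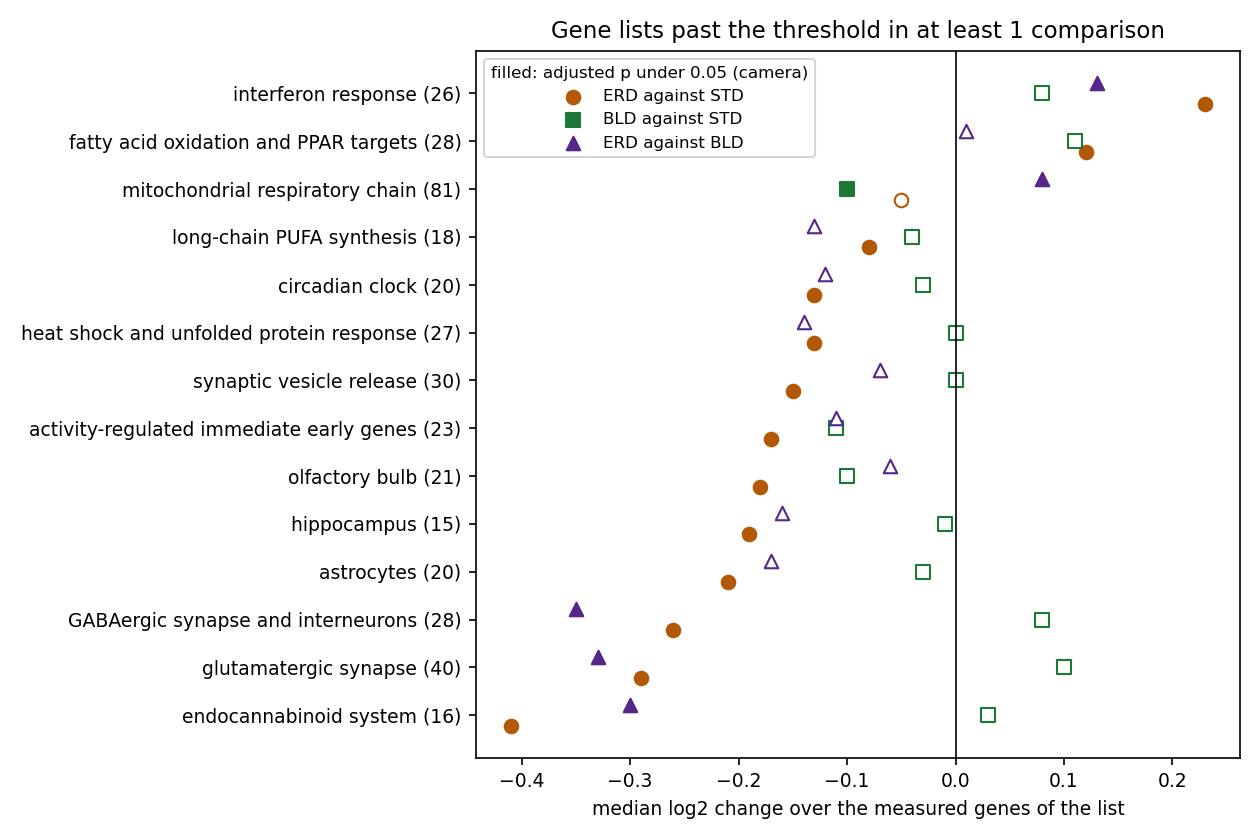
Median log2 change over the measured genes (horizontal) of each gene list that passed camera in at least 1 comparison (vertical, with the number of measured genes), for ERD against STD, BLD against STD and ERD against BLD; filled symbols have an adjusted p under 0.05, which none keeps with an estimated correlation. The endocannabinoid list has the lowest median of ERD against STD (-0.41) and the interferon list the highest (0.23); from the processed signals of the scanner software the endocannabinoid, glutamatergic, GABAergic and interferon medians of ERD against BLD turn to 0.07, 0.14, 0.07 and -0.07, and the endocannabinoid, glutamatergic and GABAergic medians of BLD against STD to -0.14, -0.37 and -0.49. With a normexp offset of 1 the endocannabinoid and glutamatergic medians of ERD against BLD turn to 0.05 and 0.14, and from Cy5 alone the vesicle median of ERD against STD turns to 0.02.

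The comparison of BLD with STD asks the same of the balanced diet. Raly was 4.68-fold higher in BLD, with a log2 change of 2.23 ± 0.22 (SE). Its group means were 0.76 ± 0.12 in BLD and -1.47 ± 0.58 in STD (SD, n = 5 each, no overlap). Genes of the mitochondrial respiratory chain fell in BLD, with 55 of 81 lower and a median of -0.10 (adjusted p = 5.51e-06 in camera, and adjusted p = 0.554 with an estimated correlation). Among genes that did not pass, Cntfr was at 2.10 (adjusted p = 0.0782, but 0.98 from the processed signals of the scanner software), Lsm14b at 1.20 (0.0516), Rnf10 at 0.71 (0.0753) and Prmt5, an arginine methyltransferase, at 0.66 (0.0829).

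In limma, 2 genes passed between BLD and STD, both higher, namely Raly (adjusted p = 0.00075) and the probe A_55_P2037525 without a symbol (0.92, adjusted p = 0.0328). An unadjusted p under 0.05 was reached by 2442 genes, 1745 higher and 697 lower. The arrays of both diets did not overlap in 2.89% of genes, where chance gives 0.79%. The other genes with low p that were higher in BLD were Anp32a (0.98, adjusted p = 0.12), Celf3 (1.53), Zic2 (1.02, on 3 STD arrays above background), Ly6a (0.90), Rhog (0.78), Ube4a (0.76) and Kdm2a (0.69), each with an adjusted p of 0.13 where none is given. Those lower were Trim41 (-0.77, adjusted p = 0.0886), Slc49a4 (-0.85, 0.0886), Pde5a (-1.27, on 4 of 5 BLD arrays), Mapk10 (-0.77), Atp9a (-0.56), Gdap1l1 (-0.60), Faim2 (-0.89), Abcb9 (-0.66), Npdc1 (-0.79) and Sly (above background on 2 of 5 BLD arrays, so that the size of its change was hardly measurable), with adjusted p between 0.13 and 0.179 from Pde5a on. From the processed signals Celf3 (0.72) was smaller, and Zic2 (1.56), Slc49a4 (-1.77), Pde5a (-2.80) and Bcas1 (-1.04) were larger. The myelin genes Mag (-0.65, adjusted p = 0.164) and Bcas1 (-0.55, adjusted p = 0.179) were among them. Further probes of Lsm14b (0.04), Anp32a (0.03), Kdm2a (0.03), Mapk10 (0.42), Atp9a (0.17) and Gdap1l1 (0.00) did not follow the one tested. Fads1 was at 0.18 (adjusted p = 0.811), Fads2 at -0.05 (0.873), Elovl2 at -0.03 (0.984), Elovl5 at 0.16 (0.586), Mfsd2a at 0.01 (0.993) and Bdnf at 0.08 (0.832). From the processed signals Fads2 was at -0.24, Elovl2 at -0.81, Mfsd2a at -0.20 and Bdnf at -0.02, and from Cy5 alone Fads1 was at -0.06, Mfsd2a at -0.34 and Bdnf at -0.19.

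Raly passed in BLD whichever array was left out (highest adjusted p 0.0054). It was at 2.19 with slide as a fixed block (adjusted p = 0.348), at 2.25 with scan day as a fixed block (adjusted p = 0.0171) and at 2.28 on slide 7, the only slide with arrays of both diets. Raly lost its call from Cy5 alone (1.86, adjusted p = 0.0725) and on the earlier scan day alone (2.26, adjusted p = 0.315). For genes past the threshold, BLD against STD, the count of 2 became 10 without STD 1, 8 without BLD 1, 7 without ERD 1, 4 without BLD 3, 3 without STD 2 and 1 without any 1 of BLD 2, BLD 4, BLD 5, ERD 2, ERD 4, STD 3, STD 4 or STD 5.

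By complex, the median of the respiratory chain genes in BLD was -0.16 in complex I (27 of 36 genes lower), -0.14 in complex II (3 of 4), -0.13 in complex III (6 of 8), and -0.07 in complexes IV (9 of 16) and V (10 of 17). The member with the lowest p went the other way, since Uqcrc1, a core subunit of complex III, was at 0.72 (adjusted p = 0.179). Cox6a1 of complex IV was at -0.48 (adjusted p = 0.369). Only 1 member, Uqcrc1, passed adjusted over the list alone, and over all genes in limma 0 passed, while 18 had an unadjusted p under 0.05. The call held whichever array was left out, with slide as a block (-0.17, adjusted p = 7.74e-05) and with scan day as a block (-0.16, adjusted p = 1.16e-05). The median was -0.31 on slide 7. From Cy5 alone it was -0.41, where the median of all genes was -0.08 and cytosolic ribosomal proteins were at -0.33 (adjusted p = 4.93e-06). In ERD the list had a median of -0.05 against STD (adjusted p = 0.343, and 0.03 from the processed signals). The difference between ERD and BLD was 0.08 (adjusted p = 0.0038, and adjusted p = 0.544 with an estimated correlation). The gene lists past the threshold, BLD against STD, numbered 1 of 43, and 2 without BLD 2, BLD 4 or BLD 5. The other 42 had medians between -0.11 and 0.27 and a lowest adjusted p of 0.29. With the processed signals of the scanner software 11 lists passed in BLD against STD, all lower. Besides the respiratory chain (-0.15) these were the glutamatergic (-0.37, turned from 0.10, adjusted p = 0.00264), GABAergic (-0.49, turned from 0.08, adjusted p = 0.00193) and endocannabinoid genes (-0.14, turned from 0.03, adjusted p = 0.0264). The others were genes of vesicle release (-0.28) and monoamine signalling (-0.67) and markers of astrocytes (-0.30), of myelin (-0.26, turned from 0.05), of hypothalamus (-0.19), striatum (-0.30) and olfactory bulb (-0.41).

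The comparison of ERD with BLD asks what the enrichment in n-3 PUFA adds to a balanced ratio. Genes of the glutamatergic synapse (30 of 40 lower, median -0.33), of the GABAergic synapse (23 of 28, -0.35) and of the endocannabinoid system (13 of 16, -0.30) fell in ERD, but their medians were 0.14, 0.07 and 0.07 from the processed signals of the scanner software. With a normexp offset of 1 the glutamatergic and endocannabinoid medians were 0.14 and 0.05, and from Cy5 alone the glutamatergic one was 0.00. Respiratory chain genes rose, with 51 of 81 higher and a median of 0.08, but 0.03 without ERD 1 and 0.05 without BLD 5. Interferon response genes rose, with 18 of 26 higher and a median of 0.13, but -0.07 from the processed signals. The adjusted p in camera were 0.0038, 0.00529, 0.00529, 0.0038 and 0.00837 in that order, and each of the 5 lists had adjusted p = 0.544 with an estimated correlation.

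No gene passed in limma between ERD and BLD (0 of 22557, lowest adjusted p 0.247), while 2344 had an unadjusted p under 0.05, 598 higher and 1746 lower. The arrays of both diets did not overlap in 1.37% of genes, where chance gives 0.79%. The genes with the lowest p and higher values in ERD were Top1mt (0.46), Psmc5 (0.49), Puf60 (0.62), Dnajb12 (0.58), Zfp703 (0.67), Tnnt1 (0.83), Arfgap3 (0.36), Mvk (0.64), Eif4g1 (0.46), Ifi27l2a (0.69), Sqor (0.41) and H2-DMb1 (0.42), with adjusted p from 0.247 to 0.332. Those with lower values were Coa5 (-0.64), Ldb2 (-1.38), Lrrc55 (-1.02), Vps26b (-0.62), Spock1 (-1.17), Napg (-1.07), Map2k1 (-1.12), Tbc1d9 (-1.02), Mblac2 (-0.63), Maob (-1.43), Isca1 (-0.80) and Smarca2 (-0.74), each with an adjusted p of 0.247. Of these, Spock1 was above background on 3 of 5 ERD arrays, and Coa5, Lrrc55, Tbc1d9, Mblac2 and Maob on 4 of 5. Further probes of Coa5 (0.29), Mvk (-0.05) and Isca1 (-0.02) did not follow the one tested. From the processed signals Ldb2 (-0.40), Smarca2 (-0.47) and Arfgap3 (0.23) were smaller, and Coa5 (-1.40), Mblac2 (-1.33), Spock1 (-1.94) and H2-DMb1 (0.76) were larger. Fads1 was at -0.81 (adjusted p = 0.332), Fads2 at -0.04 (0.93), Elovl2 at -0.48 (0.583), Elovl5 at -0.24 (0.476), Mfsd2a at 0.52 (0.445) and Bdnf at -0.31 (0.425). From the processed signals Fads2 was at -0.62, Elovl2 at 0.00 and Elovl5 at -0.12, and from Cy5 alone Elovl5 was at 0.02. Puf60 and Eif4g1 thus passed in ERD against STD and not in BLD against STD, but their differences between ERD and BLD did not pass (adjusted p 0.247 and 0.303). Without STD 3, 1 gene passed in place of 0.

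Among the members with low unadjusted p were Gria2 (-1.67) and Homer2 (-0.85) of the glutamatergic genes, Gabra4 (-1.21) of the GABAergic genes, Faah (-0.46) and Napepld (-0.59) of the endocannabinoid genes, Atp5k (0.33) and Ndufa9 (0.41) of the respiratory chain, and Oas1a (0.41) and Ifih1 (0.32) of the interferon genes. Their adjusted p over all genes lay between 0.289 and 0.453. All of these synaptic and endocannabinoid members were above background on 4 of 5 ERD arrays, and Ifih1 on 3. Adjusted over the list alone 1, 1, 2, 0 and 0 members passed, and 9, 9, 6, 7 and 3 had an unadjusted p under 0.05. The interferon list lost its call without ERD 5 or BLD 5 (highest adjusted p 0.0676), and its median was 0.08 without ERD 1 and 0.21 without BLD 2. The glutamatergic median was -0.19 without ERD 1. Without the arrays of slide 3 the GABAergic (-0.30, adjusted p = 0.103), respiratory chain (0.01, adjusted p = 0.14) and interferon lists (0.07, adjusted p = 0.14) lost their calls. With Cy5 detection as a covariate the same 3 lists (-0.17, 0.05 and 0.06, adjusted p 0.145, 0.0612 and 0.205) and the glutamatergic list (-0.11, adjusted p = 0.205) did. Without the 3 least correlated arrays only the respiratory chain kept its call (0.11, adjusted p = 0.000253). The number of gene lists past the threshold, ERD against BLD, became 9 without ERD 1 and 11 without ERD 2. With slide as a block the medians were -0.39, -0.48, -0.38, 0.11 and 0.21 (adjusted p 0.000218, 0.0037, 0.00145, 0.0049 and 0.000218). With scan day as a block they were -0.35, -0.37, -0.36, 0.09 and 0.17 (0.00789, 0.0232, 0.00409, 0.0152 and 0.0114). Within slide 1 they were -0.17, -0.15, -0.27, -0.09 and 0.02, within slide 3 -0.91, -0.90, -0.61, 0.24 and 0.38, and within slide 7 -0.28, -0.05, -0.31, 0.07 and 0.24. The other 38 lists had medians between -0.22 and 0.06, with the lowest adjusted p, 0.0511, in the markers of cerebellum (16 of 20 lower, median -0.16, but 0.10 from Cy5 alone).

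The limma F test over the 3 diets called 11 genes. Among genes with a symbol the lowest p belonged to Raly (adjusted p = 0.000897), Eif4g1, Puf60 and Rnf10 (0.032 each) and Lsm14b (0.0444). Rnf10 had means of 0.52 ± 0.22 in STD, 1.23 ± 0.11 in BLD and 1.28 ± 0.13 in ERD, and Lsm14b of 0.80 ± 0.27, 2.0 ± 0.41 and 1.75 ± 0.16. Eif4g1 had -0.20 ± 0.15, 0.26 ± 0.19 and 0.71 ± 0.17 and Puf60 -0.04 ± 0.18, 0.37 ± 0.14 and 0.99 ± 0.29 (SD, n = 5 each). For genes past the threshold, any difference among the 3 diets, the count became 24 without ERD 1, 22 without BLD 1 and 18 without BLD 3. It became 5 without STD 3, 4 without BLD 5 or ERD 5, 2 without any 1 of BLD 2, BLD 4, ERD 4, STD 2 or STD 4, and 1 without STD 5.

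Both n-3 richer diets were compared with the same STD arrays. Their changes correlated across genes with r = 0.628, and genes are not independent replicates. Arrays simulated without any diet effect gave a mean of 0.499 and a highest value of 0.518 from the shared controls alone. The covariance was 0.061 against 0.0244 in the simulation. With the STD arrays split between the comparisons, r was 0.446 on average over 20 ways (0.228 to 0.59), and 23 of 100 relabellings of the arrays gave an r as large. Raly and A_55_P2037525 were called in both comparisons, both higher, with the same STD arrays in each.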

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

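All tests of single explanations in this part were chosen after the result was seen, except the reference channel and the abundance of the transcripts for the respiratory chain genes; the counts over other splits of the arrays were planned.

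For the 49 genes called between ERD and STD, 1 of 100 splits of the 10 arrays into 5 and 5 gave as many genes, the real one. The highest other split gave 2. Chance was made unlikely but is not excluded, as 1 of 100 is the lowest share that these splits can give. On the earlier scan day the median change of these genes was 0.98 of that on all arrays. Of the ERD and STD arrays, on which the genes had been chosen, that fit left out only ERD 4. It therefore cannot decide on scan day as the cause. There 0 passed, because the standard errors grew to a median of 1.11 times and fewer arrays were used. Without the 3 least correlated arrays the median change was 0.99 of its size. Of the ERD and STD arrays this left out only ERD 1 and ERD 4, so it cannot decide on poor arrays as the cause. Again 0 passed, as the standard errors were 1.16 times as large. Signal of a single probe may account for part of the calls, since over the 10 called genes with another measured probe the other probes showed a median of 0.14 of the called change, and in 4 of them the other way; among the next 500 genes the 106 with another measured probe gave a median of 0.23 as well. With slide as a fixed block the median change was 0.93 of its size. The genes had been chosen on these same arrays, which by itself keeps the ratio high, so it cannot decide on slide as the cause. With that block 0 passed, as the standard errors were 1.12 times as large and fewer degrees of freedom remained. A response to the diet stays open for these genes.

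For the lists in ERD against STD, 14 of 100 splits gave as many as the 13 called, and the highest other split gave 20, so chance cannot be excluded for their number. For the 11 lists of neuronal and other genes that fell, the median shift on the earlier scan day was 0.99 of its size (0.81 to 1.56). Only 4 of these calls remained there. Of the ERD and STD arrays that fit left out only ERD 4, so it cannot decide on scan day as the cause. The dye normalization cannot be told apart from the diet for these lists. With the processed signals of the scanner software the SD of changes over all genes grew from 0.33 to 0.63, so the median shift was 1.15 of its size in log2 (0.65 to 3.24) but 0.61 relative to that SD (0.34 to 1.71), and all 11 calls ended. Array quality cannot be told apart from the diet for these lists, since without the 3 least correlated arrays the median shift was 0.79 of its size but ranged from 0.26 to 1.51, and ERD 1 carried much of the shift of the synaptic genes. A response to the diet stays open.

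For the respiratory chain genes in BLD, 78 of 100 splits gave as many lists as the 1 called between BLD and STD (highest other 7), so chance cannot be excluded for the number of lists. On the earlier day the median change was 2.37 times that on all arrays, which argues against the later day as the source of the whole shift. It rests there on BLD 1 and BLD 5 alone, with list means of -0.11 and -0.17. The later-day arrays BLD 2, BLD 3 and BLD 4 had list means of -0.03, 0.03 and -0.01, and the STD mean was 0.07. The reference channel as the cause would need the list to rise in Cy3, and there it fell by 0.15 relative to all genes (value -0.15, bootstrap SE 0.015). Of 10000 random lists matched on Cy5 level, 0.75% had a median as low. Random lists lack the correlation between the genes of this list (estimated at 0.061), so this share cannot decide on high abundance of these transcripts. High abundance, a shift shared by both channels, and a response to the diet stay open.

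For the 2 genes called between BLD and STD, 2 of 100 splits gave as many, the real one included. A split that mixed the diets was among them, with a highest other of 2, so chance was made unlikely but is not excluded. For the F test, 3 of 100 relabellings gave as many as the 11 genes, the real one included. That share made chance unlikely without excluding it, as the highest other relabelling gave 794 genes. So many genes point to a structure of the arrays. That relabelling set ERD 2, ERD 4, BLD 2, BLD 3 and BLD 5, among them 3 of the 4 arrays of the later scan day, against ERD 5 with STD 2 to STD 5 and against the other arrays. These 3 arrays, ERD 4, BLD 2 and BLD 3, were also those of slide 1. The F test called 3 genes with scan day as a fixed block. For the 5 lists of ERD against BLD, 38 of 100 splits gave as many (highest other 18), so chance cannot be excluded for their number. The 0 genes found in that comparison are reached by all 100 splits by construction, so their count tests nothing. The highest other split there called 1087 genes by setting ERD 1, ERD 3, ERD 5, BLD 1 and BLD 5 against the 4 arrays of the later scan day and ERD 2. That split follows the scan day except for ERD 2. As 3 of the 4 later arrays were on slide 1, it cannot tell scan day from slide. With scan day as a fixed block ERD against BLD had 0 genes and 8 lists.

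Single arrays stood apart from the other 4 of their diet in 17 of 261 groups of values (6.5%, where chance gives about 5%), measured by the gap to the nearest other array as a share of the range. Raly was -0.46 on STD 1 and -1.84 to -1.49 on the other STD arrays (gap 0.752). Creg2 was 1.93 on ERD 2 (others 0.55 to 0.88, gap 0.76). Ndn was 0.67 on ERD 1 (1.39 to 1.64, gap 0.739). Srp9 was 0.10 on STD 5 (-0.61 to -0.45, gap 0.774). Acap2 was -0.55 on ERD 5 (-1.26 to -1.06, gap 0.718). Strap was 0.14 on BLD 1 (-0.62 to -0.53, gap 0.875). Ly6a was -1.66 on ERD 1 (-0.98 to -0.71, gap 0.72). Slc49a4 was -0.15 on ERD 5 (-0.42 to -0.34, gap 0.714). Pde5a was -0.77 on STD 1 (0.43 to 0.66, gap 0.836). Atp9a was 4.07 on BLD 1 (4.37 to 4.48, gap 0.728). Dnajb12 was -0.27 on STD 3 (-0.73 to -0.63, gap 0.77). Tnnt1 was 0.93 on ERD 1 (0.12 to 0.35, gap 0.716). Maob was 2.20 on BLD 2 (2.88 to 3.10, gap 0.756). Elovl2 was 1.39 on STD 4 (1.78 to 1.92, gap 0.736), and Elovl5 was 0.22 on STD 1 (-0.23 to -0.10, gap 0.725). The mean of the heat shock and unfolded protein response list was -0.14 on BLD 5 (0.05 to 0.12, gap 0.732), and that of the astrocyte markers 0.20 on STD 2 (0.00 to 0.05, gap 0.738).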

How the results depend on the processing

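Fits with offset 1, scan day as a fixed block, the earlier scan day, slide 3 left out, the 3 least correlated arrays left out and Cy5 detection as a covariate were chosen after seeing the data. No paired analysis was possible because each animal gave 1 array and replicate numbers only name samples, so slide was used as a block, with ERD and STD arrays together on slides 4, 5 and 7 only. The direction of the 49 genes called between ERD and STD was the same in every setting tabulated that measured them, and 0 called values changed sign. These settings refit the arrays on which the genes were chosen, so the same direction was likely beforehand. Of the values of single named genes over the settings, 2700 stayed on their side of the threshold (39 of them, all uncalled, with another sign), 381 lost a call and 48 gained one. The cause was not tested where a setting below changed a count, except that a looser threshold, fewer arrays or fewer degrees of freedom change it by construction. Signal over background limits dim genes, since the median net Cy5 intensity of an array was between 12.2 and 22.9, and Cy5 alone moved the median change of all genes in ERD against BLD from -0.041 to 0.115.

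There were 49 genes past the threshold, ERD against STD, 2 genes past the threshold, BLD against STD, 0 genes past the threshold, ERD against BLD, and 11 genes past the threshold, any difference among the 3 diets (F test). The lists of these comparisons numbered 13, 1 and 5, and the correlation of the ERD and BLD changes against STD was 0.628. Values below keep this order. Without each array in turn, genes ranged from 5 to 170, 1 to 10, 0 to 1 and 1 to 24, lists from 5 to 20, 1 to 2 and 4 to 11, and the correlation from 0.506 to 0.745. With processed signals of Feature Extraction, and with the deposited value table, BLD against STD had 1 gene and 11 lists, all lower, ERD against BLD 3 lists, ERD against STD 0 lists and the F test 1 gene, and 13 of the 49 genes remained called. With the Cy5 channel alone ERD against STD had 2 genes and 1 list, BLD against STD 1 gene and 2 lists, the F test 0 genes and the correlation was 0.704. That gene of BLD against STD was neither of the 2 called in the main fit. With a normexp offset of 1 ERD against STD had 2 lists, BLD against STD 1 gene and 2 lists, ERD against BLD 0 lists and the F test 1 gene. With no filter on dim probes BLD against STD had 5 genes and ERD against BLD 14 lists; with probes well above background in both channels on all arrays lists numbered 3, 2 and 1 and BLD against STD had 4 genes. With slide as a fixed block genes numbered 1, 0, 1 and 1, lists 5, 4 and 13, and the correlation was 0.527; as a random block ERD against STD had 101 genes, BLD against STD 7 and the F test 63. With scan day as a fixed block ERD against STD had 11 genes and 8 lists, BLD against STD 1 gene and 2 lists, ERD against BLD 8 lists, the F test 3 genes and the correlation was 0.468. With arrays of the earlier scan day only genes numbered 0, 1, 1 and 1, lists 5 and 3 against STD, and the correlation was 0.363. There too the gene of BLD against STD was neither of the 2 called in the main fit. With slide 3 left out genes numbered 86, 31 and 59 in the F test, lists 6 in ERD against STD and 3 in ERD against BLD, and the correlation was 0.756. With the 3 least correlated arrays left out ERD against STD had 0 genes and 5 lists, ERD against BLD 1 list and the F test 1 gene. With Cy5 detection as a covariate ERD against STD had 92 genes and 5 lists, ERD against BLD 2 lists, the F test 45 genes and the correlation was 0.73. Array weights gave 216, 36 and 123 genes in ERD against STD, BLD against STD and the F test, an adjusted p under 0.10 gave 164, 11 and 65, and eBayes with trend and robust gave 9 in BLD against STD and 25 in the F test. With only the groups compared genes numbered 22, 1 and 1, and an unadjusted p under 0.05 with a 1.5-fold change gave 1054, 697 and 736. Camera with an estimated correlation called 0, 0 and 0 lists, the direction p of fry 3, 0 and 0, and its mixed p 14, 0 and 0. With the STD arrays split between the comparisons the mean correlation was 0.446.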

Other observations

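The tests of scan day in this part were chosen after the split by scan day was seen, and the genes beyond the rule for named genes were chosen after their values were seen.

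Antioxidant genes of the NRF2 list moved both ways in ERD against STD, so the list did not pass (median 0.03, and -0.07 from the processed signals, adjusted p = 0.823 in camera), although 6 of 29 members passed adjusted over the list alone, 4 higher and 2 lower. Prdx5 passed over all genes in limma (0.75, adjusted p = 0.0401), while Gstm5 (0.66, adjusted p = 0.117) and Gstp1 (0.53, adjusted p = 0.147), which conjugate glutathione, Gpx4 (0.52, adjusted p = 0.181), which reduces lipid peroxides, and on the lower side Sod2 (-0.46, adjusted p = 0.124), the mitochondrial superoxide dismutase, and Gsr (-1.12, adjusted p = 0.161), glutathione reductase, did not. Among glucocorticoid-responsive genes Angptl4, a target of both the glucocorticoid and the PPAR receptors, was at 0.82 (adjusted p = 0.0895) and Nr3c1, the glucocorticoid receptor, at -0.74 (adjusted p = 0.132), and 3 of the 19 members passed adjusted over the list alone (list adjusted p = 0.395).

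Genes of DNA methylation and one-carbon metabolism did not pass as a list in ERD against BLD (median -0.03, adjusted p = 0.747 in camera), but 4 of 25 members passed adjusted over the list alone, all lower and none over all genes in limma. Among them were Dnmt3a (-0.76, adjusted p = 0.319), a de novo DNA methyltransferase, Mbd2 (-0.39, adjusted p = 0.34), which binds methylated DNA, and Mat2b (-0.49, adjusted p = 0.332), a subunit of the enzyme that makes S-adenosylmethionine. The genes next to Raly on the chromosome did not rise with it in ERD against STD, as Chmp4b was at -0.41 (adjusted p = 0.435) and Eif2s2 at 0.07 (adjusted p = 0.881). The 4 genes beyond these were Zfp341 (-0.15), Pxmp4 (-0.03), Itch (-0.83, adjusted p = 0.224) and Dynlrb1 (0.08), and 0 of the 6 passed in either comparison with STD.

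With diet in the limma model, 1017 of 22557 genes differed between the later and the earlier scan day, 923 higher and 94 lower (lowest adjusted p 0.000169). Of the 49 genes called between ERD and STD, 0 were among them. At that share few of 49 genes would be among them anyway, so the 0 does not clear these genes of a scan day effect. The later day held 4 arrays and no STD array, so scan day and BLD in part overlap. Of these arrays ERD 4, BLD 2 and BLD 3 were on slide 1, so scan day and slide overlap as well. In the Cy3 channel alone, which carries the same reference on every array, 0 genes were called in ERD against STD, 15 in BLD against STD and 0 in ERD against BLD. The 15 exceed the 2 genes called from the ratio in BLD against STD, and their cause was not tested.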
